A study of Mus musculus with 8 samples.

How the data were processed

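Gene expression was measured on 8 single-colour microarrays, each hybridised with biotin-labelled cDNA made from 200 ng of total RNA with an Affymetrix whole-transcript kit, per the labels' protocols. RNA had been isolated with TRI Reagent from sorted splenic CD4+CD25- T cells of C57BL/6 mice aged 6 to 8 weeks, wild type or CCR2-/-. The groups were read from the sample titles: 2 arrays each for CD45RBhigh and CD45RBlow cells of each genotype. A number 2 stands in the titles of 4 samples, and the samples without a number were taken as replicate 1. No label says that replicates came from separate animals, so p-values measure only the spread between these samples.

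The deposited values are log2 expression values of 41034 transcript clusters, made by the authors with RMA and Partek, per the submitters' processing notes, which give neither versions nor options. The values ran from 3.07 to 13.92 on the log2 scale, which fits RMA output, and were used as deposited. RMA sets all arrays to a common distribution, so a change shared by most genes would not show. Scanner files and a genome were not used here. Arrays have no read depth, and their number limits the precision: the median standard error of a gene's log2 difference was 0.15 between groups of 2, 0.10 for an effect averaged over both genotypes or both subsets, and 0.21 for the interaction.

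Gene names came from the platform's probe annotation. It listed 25335 of the clusters, 23521 with exactly 1 gene symbol and 1814 with several, and 15699 clusters were unnamed here. Of the entrez identifiers, 23328 matched the mouse RefSeq table of GRCm38.p6 and 193 did not, which changed 0 symbols. Clusters with several symbols were left out. The brightest cluster stood for each of the 1082 genes that had several, which left 22180 genes. Genes at or above an array's 40th percentile of all clusters on at least 2 arrays were tested, 13508 in all.

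A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 over all 8 arrays (4 residual degrees of freedom, 3.36 prior degrees of freedom), with default empirical Bayes settings. The 7 comparisons were the genotype effect in each subset, the subset effect in each genotype, their interaction, and the genotype and subset effects averaged over the other factor. P-values are limma's moderated ones, two-sided, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Genotype effects are CCR2-/- minus wild type and subset effects are CD45RBlow minus CD45RBhigh.

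Before the data were examined, 23 pathway lists and 11 lists of cell type markers were fixed, together with the tests and the rule for naming genes. The 29 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The other lists had too few tested members: 4 sex-linked genes, 2 gamma-delta and NKT cell markers, 2 neutrophil markers, 2 platelet markers and 0 erythroid markers. Camera with an estimated correlation and the self-contained fry test were alternatives. Lists overlap, so a gene such as Il21, Cxcr3 or Ccr7 counts in several.

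The genes named for a comparison were up to 10 with the largest increase and up to 10 with the largest decrease among those that passed, with group values that did not overlap or, for averaged effects, the same sign in both strata. Where fewer than 10 genes passed, the 10 with the smallest p were named. Up to 4 passing members of each list were added, or 2 members with the smallest p where none passed, along with a fixed set around CCR2, CD45, CD4 and the helper cytokines. Gene models without a usual symbol were counted but not named.

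Replicate numbers were checked for pairing before the fits were compared. Across genes, the difference of replicate 2 from replicate 1 correlated between every 2 of the 4 groups, with 6 correlations from 0.11 to 0.53, all over the limit of 0.1 set for pairing, so the numbers were taken to pair the samples. No label says what the number marks, and the main fit held no term for it. The main fit therefore counts a difference between numbers that the groups share as spread within groups, which makes its tests less sensitive. A fit with the replicate number as a block is therefore given where it changes the call of a gene or list named in the text or moves a count of genes given there, over all genes or within a list, by more than 1.5 times.

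The calculations were tested on simulated arrays with the real genes' means and with variances drawn from the distribution that limma fitted. For the genotype effect in CD45RBhigh, 65 of 100 genes changed by 1 log2 unit and 97 of 100 changed by 2 log2 units were recovered, with 8 false calls among 13308 unchanged genes. For the averaged subset effect, 85 of 100 and 100 of 100 were recovered, with 12 false calls among 13308. A list of 20 genes shifted by 0.5 log2 units was called, and 0 of the other lists. Simulated genes varied independently, so this does not cover correlated genes. The simulation also held no difference between replicate numbers and gave a gene the same spread in all groups.

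Alternatives were the filter on dim genes, median centring, quantile normalization, the empirical Bayes options, array weights, the replicate block, a fit on the compared groups alone for the 4 effects between 2 groups, other rules from cluster to gene, a threshold of unadjusted p under 0.05 with a 1.5-fold change, and leaving out each array in turn. Leaving out both CCR2-/- replicate 2 arrays, and leaving out X and Y chromosome genes, were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.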

Results

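Transcript levels were measured in splenic CD4+CD25- T cells sorted by their surface level of CD45RB, an isoform of the leukocyte phosphatase CD45 that is high on naive T cells and lower on antigen-experienced ones. The cells came from wild-type mice and from mice without CCR2, the receptor for the chemokine CCL2, and were stimulated with antibodies to CD3 and CD28. The sample protocols give 48 h of stimulation and the series design gives 2 h, so the labels do not settle the duration. The 33 tested cell cycle genes averaged 10.4 to 10.6 on the log2 scale on all arrays, far over the array medians. This argues against 2 h, when resting T cells would not yet divide, but no unstimulated cells were measured. Each of the 4 combinations of genotype and subset had 2 arrays. Array medians lay between 4.92 and 5.05 on the log2 scale, and the arrays of a group correlated across clusters at r = 0.984 to 0.994. The leading principal component held 45.5% of the variance and separated all CD45RBlow arrays (scores from 4.43 to 25.7) from all CD45RBhigh arrays (scores from -26.8 to -8.56). The next component held 23.5% and separated all replicate 1 arrays (scores from -25.9 to -1.61) from all replicate 2 arrays (scores from 4.90 to 16.1).

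Ccr2, the targeted gene, had low values on most arrays. Its log2 level was 4.36 ± 0.13 in wild-type CD45RBhigh cells, 4.56 ± 0.06 in wild-type CD45RBlow cells, 4.68 ± 0.09 in CCR2-/- CD45RBhigh cells and 4.93 ± 0.32 in CCR2-/- CD45RBlow cells (mean ± SD, n = 2 each). These levels lay between the 27.0th and the 53.5th percentile of all clusters, the highest in CCR2-/- CD45RBlow replicate 1. Which part of Ccr2 is deleted and which exons the probes cover is not known here, so the values do not check the genotype labels. Cd4 lay between the 98.2nd and the 98.7th percentile on all arrays. Neither Cd4 (log2 difference 0.02, adjusted p = 0.932) nor Ptprc, the gene of CD45 (0.05, adjusted p = 0.830), passed the test between subsets.

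The replicate numbers differed in the sex-linked genes. Xist, which is expressed from the inactive X chromosome of females, had log2 levels from 4.45 to 5.02 on the replicate 1 arrays and from 11.7 to 12.1 on the replicate 2 arrays. Kdm5d, on the Y chromosome, was at 8.83 to 9.13 on the replicate 1 arrays and at 7.58 to 7.78 on the replicate 2 arrays. Each group held an array of each number, so this difference is part of the spread within every group. It argues against the same mice behind both numbers, although no label gives the sex or the number of mice.

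The comparison of CD45RBlow with CD45RBhigh cells, averaged over the genotypes, asked how the sorted populations differed. Some cytokines and transcription factors of regulatory and helper T cells, such as Il10, Foxp3, Maf and Il4, had more transcript in CD45RBlow cells, while Ifng, Il17a, Il2 and Tbx21 did not pass. Il10, an anti-inflammatory cytokine, rose 11.96-fold (log2 3.58, 95% confidence interval 2.72 to 4.44, adjusted p = 0.0075), and Foxp3, the lineage factor of regulatory T cells, rose 8.30-fold (3.05, interval 2.35 to 3.76, adjusted p = 0.0063). Foxp3 went from 5.58 ± 0.30 to 8.79 ± 0.49 in wild type and from 5.60 ± 0.41 to 8.49 ± 0.88 in CCR2-/- cells (mean log2 level ± SD, n = 2 each). Maf rose 5.83-fold (adjusted p = 0.0018) and Il4 rose 3.70-fold (adjusted p = 0.0044). Ccr7, Dapl1, Asns and Ddit3 were among the genes with more transcript in CD45RBhigh cells. Limma called 409 genes in all, 148 higher and 261 lower in CD45RBlow cells.

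The other large increases were in Akr1c18 (log2 3.51), Il21 (3.49), Il9 (2.98), Itgb8, an integrin subunit that activates TGF-beta (2.82), Ahr, the aryl hydrocarbon receptor (2.72), Il1r2, a decoy receptor for interleukin 1 (2.68), and Gpr33 (2.61). Il21 varied widely among wild-type CD45RBhigh arrays (6.91 ± 2.52, n = 2). Among regulatory T cell genes, 7 of 19 rose, including Ikzf2 (2.49), Ctla4 (1.13) and Gpr83 (1.23) besides Foxp3 and Il10; adjusted over the list alone, 10 were higher and 1 was lower. The list was called up (mean 0.89, adjusted p = 1.17e-07; adjusted p = 0.281 with an estimated correlation). Il2ra, which encodes the CD25 against which the cells were sorted, differed by 0.10 (adjusted p = 0.591). Its log2 level was 12.2 to 12.5 on all arrays. The cells had been stimulated, so this level does not check the sort. Of 11 Th2 genes 7 rose, including Il4, Il9, Il13 (2.07) and Il24 (2.12), while Gata3, the Th2 lineage factor, rose by 0.73 on the log2 scale (adjusted p = 0.0244). Adjusted over the list alone, 8 Th2 genes were higher and 2 lower, and the list was called up (mean 0.76, adjusted p = 1.09e-05; adjusted p = 0.281 with an estimated correlation).

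Of 12 Th17 genes 3 rose, namely Il21, Ahr and Il23r (0.65), 5 rose with the replicate block, and 5 were higher adjusted over the list alone. Il23r was dim, at 4.12 to 5.15 on the log2 scale. The Th17 list was called up (mean 0.97, adjusted p = 2.65e-05; adjusted p = 0.281 with an estimated correlation), while Il17a itself differed by 0.79 (adjusted p = 0.241). Of 30 cytokine genes 8 rose and Fasl fell by 1.10; adjusted over the list alone, 10 were higher and 4 lower (mean 0.45, adjusted p = 0.0305; adjusted p = 0.412 with an estimated correlation, and adjusted p = 0.0613 with the replicate block, where 8 rose and 2 fell). The cytokine call was also lost without wild-type CD45RBlow replicate 1 (adjusted p = 0.0846), CCR2-/- CD45RBhigh replicate 1 (adjusted p = 0.195) or CCR2-/- CD45RBlow replicate 1 (adjusted p = 0.0875). Ifng differed by 1.13 (interval 0.31 to 1.95, adjusted p = 0.142). Among memory and effector genes, 4 of 28 rose, namely Maf, Prdm1 (1.67), Id2 (1.56) and Cxcr3 (1.18), with 9 higher and 1 lower with the replicate block and 9 higher adjusted over the list alone (adjusted p = 4.63e-04; adjusted p = 0.382 with an estimated correlation). Cd44, a usual surface marker of memory cells, differed by -0.28 (adjusted p = 0.189).

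**Figure D1:**
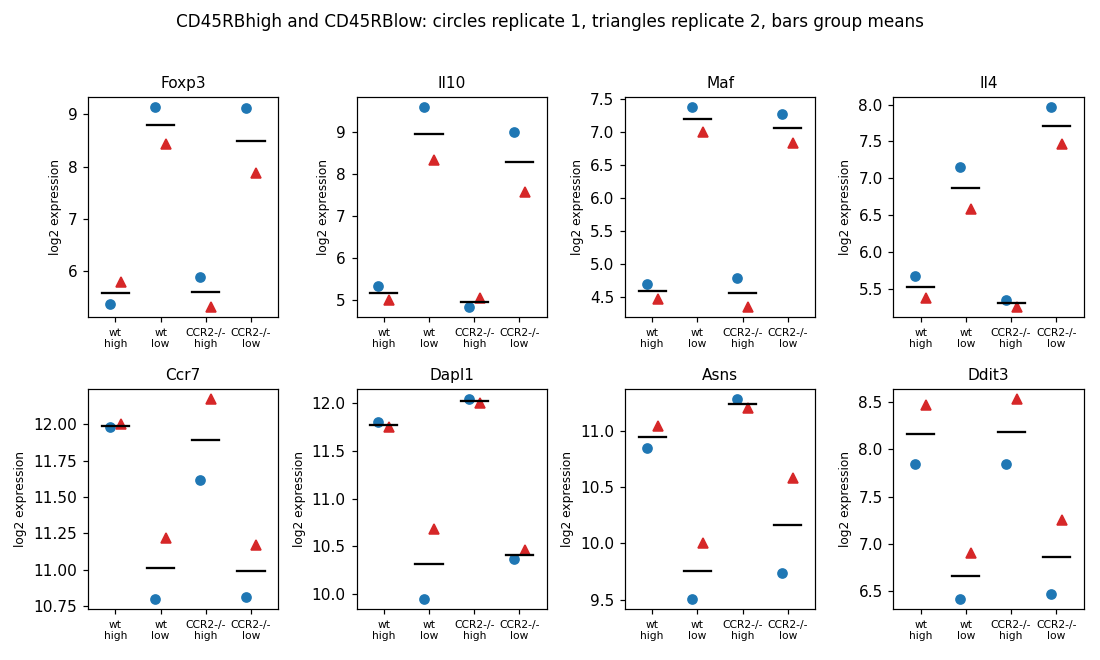
Log2 expression (vertical axis) of 8 genes in the 4 groups (horizontal axis), where each point is an array, circles are replicate 1, triangles are replicate 2 and bars are group means of 2 arrays. Foxp3, Il10, Maf and Il4 were higher and Ccr7, Dapl1, Asns and Ddit3 lower in CD45RBlow cells of both genotypes.

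Smaller groups rose in part. Il21 and Sostdc1 (0.72) rose among 12 follicular helper genes, with 4 higher adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.281 with an estimated correlation). Of 16 inhibitory receptor genes 3 rose, Ctla4, Entpd1 (0.87) and Havcr2 (0.68), with 4 higher adjusted over the list alone (adjusted p = 0.0063, and 0.320 with an estimated correlation). Havcr2 was dim, at 4.51 to 5.52 on the log2 scale. Itgb8, Tgfbr3 (0.68) and Ski (0.57) rose among 18 TGF-beta pathway genes, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0107; adjusted p = 0.281 with an estimated correlation). Among 12 chemokine receptor genes Cxcr3 and Ccr4 (1.004) rose and Ccr7 fell, and 5 were higher and 1 lower adjusted over the list alone (mean 0.24, adjusted p = 0.0063; adjusted p = 0.320 with an estimated correlation). With the replicate block 4 chemokine receptor genes rose, and without CCR2-/- CD45RBhigh replicate 1 the list mean was 0.15.

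The largest decreases were in Ms4a4b (log2 -2.98), Amigo2 (-2.45), Slc7a3, a transporter of cationic amino acids (-2.42), Trim30d (-2.36), Aldh1l2 (-2.05), Pck2 (-2.04), Ms4a4c (-1.94), Trat1 (-1.92), Gpt2 (-1.91) and Phf11b (-1.88). Among 20 naive and quiescence genes 5 fell, including Dapl1 (-1.53), the lymph node homing receptor Ccr7 (-0.94), Actn1 (-0.88) and Klf3 (-0.80). Adjusted over the list alone, 8 were lower and 1 higher (mean -0.35, adjusted p = 0.0031; adjusted p = 0.337 with an estimated correlation). Of 19 genes of the unfolded protein and amino acid stress response 4 fell, Ddit3, which encodes CHOP (-1.42), Asns, asparagine synthetase (-1.14), Herpud1 (-0.94) and Mthfd2 (-0.66), against 8 with the replicate block, with 11 lower adjusted over the list alone. That list was called down (mean -0.55, adjusted p = 8.40e-06; adjusted p = 0.281 with an estimated correlation). No cholesterol synthesis gene passed limma's test of single genes among 16, 3 fell with the replicate block, 5 were lower and 1 higher adjusted over the list alone, and the list was called down (mean -0.23, adjusted p = 0.0037; adjusted p = 0.490 with an estimated correlation), a call lost without CCR2-/- CD45RBhigh replicate 1 (adjusted p = 0.0503).

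The interferon-response genes had the lowest list mean in CD45RBlow cells (-1.15, camera adjusted p = 3.90e-08; adjusted p = 0.412 with an estimated correlation), but among 26 limma called only Oas2 (-0.63), at levels near the floor of the array, and 8 genes with the replicate block. Adjusted over the list alone, 17 were lower. Without CCR2-/- CD45RBhigh replicate 2 the list mean was -0.69. The gap between subsets varied from -0.16 in CCR2-/- replicate 1 to -1.80 in CCR2-/- replicate 2, with -1.03 and -1.61 in wild-type replicates 1 and 2. Camera also called 3 lists of markers of other cells down, B cell, dendritic cell and macrophage and monocyte markers, but not NK cell or CD8 T cell markers. Ighm fell by 1.03 among 11 B cell markers (2 fell with the replicate block), the single member lower adjusted over the list alone (mean -0.65, adjusted p = 0.0013; adjusted p = 0.412 with an estimated correlation), while its 6 dimmer clusters differed by -0.37 to 0.01. Ccr7 and Naaa (-0.73) fell among 6 dendritic cell markers, with 4 lower adjusted over the list alone (mean -0.54, adjusted p = 0.0011, and 0.281 with an estimated correlation). Of these markers, Ccr7 is also listed with the naive and quiescence genes and Bst2 with the interferon-response genes. The dendritic cell call is therefore not separate from the calls of those lists. Among 7 macrophage and monocyte markers Ctss, encoding cathepsin S, fell (-1.23), also the only member lower adjusted over the list alone (adjusted p = 0.0479; adjusted p = 0.337 with an estimated correlation), and 2 fell with the replicate block. The macrophage and monocyte call was lost without wild-type CD45RBhigh replicate 1 (adjusted p = 0.140), CCR2-/- CD45RBhigh replicate 1 (0.118), CCR2-/- CD45RBlow replicate 1 (0.0998), wild-type CD45RBlow replicate 2 (0.151) or CCR2-/- CD45RBlow replicate 2 (0.0585). The mean B cell marker gap went the other way over the replicates, with -0.95 and -1.32 in replicate 1 of wild type and CCR2-/-, and -0.11 and -0.23 in replicate 2. The gap of Ighm did not, and was larger in replicate 2 of both genotypes.

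**Figure D2:**
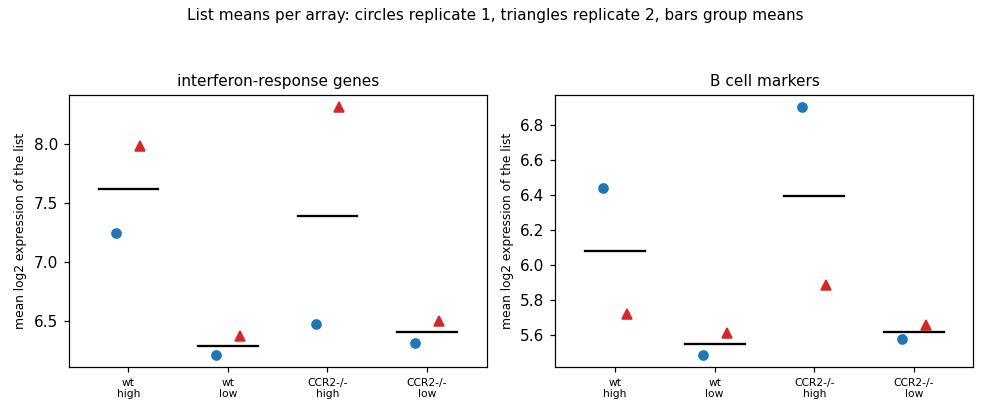
Mean log2 expression (vertical axis) of the 26 tested interferon-response genes and the 11 tested B cell markers on each array, by group (horizontal axis), with circles for replicate 1, triangles for replicate 2 and bars for group means. The interferon mean was highest on the replicate 2 CD45RBhigh arrays (7.98 and 8.31), and the B cell mean on the replicate 1 CD45RBhigh arrays (6.44 and 6.90).

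Activation and growth programmes were not called between subsets. Among 24 T cell activation genes Egr2 rose (0.79) and Nr4a3 fell (-0.63), with 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.800). Il2 differed by 0.28 (adjusted p = 0.690) and the Th1 factor Tbx21 by 0.19 (adjusted p = 0.685). Of 16 Th1 genes Cxcr3 and Havcr2 rose while Fasl and Stat4 (-0.66) fell (list adjusted p = 0.565), with 4 higher and 3 lower adjusted over the list alone. Fasl, its receptor Fas (-0.73) and Bbc3 (-0.43) fell among 19 apoptosis genes, and these 3 were also the count adjusted over the list alone (list adjusted p = 0.140 by camera, and 0.0041 by fry, which does not compare the list with other genes). Socs2 rose (1.37) among 19 IL-2 and STAT5 targets (list adjusted p = 0.957). Among 15 cytotoxicity genes Ctsw rose (1.01) and Fasl and Serpinb6b (-1.10) fell (list adjusted p = 0.853). Als2cl fell (-0.72) among 19 genes near Ccr2 on distal chromosome 9 (list adjusted p = 0.713). The remaining lists had no member called by limma: cell cycle (adjusted p = 0.984), oxidative phosphorylation (0.505), glycolysis and hypoxia (0.539), chemokines (0.639), CD8 T cell markers (0.281), NK cell markers (0.385) and CD4 T cell markers (0.682). With the replicate block, 2 activation genes rose and 2 fell, 2 cytotoxicity genes rose and 3 fell, 2 IL-2 and STAT5 targets rose and 1 fell, and 1 gene near Ccr2 rose and 2 fell. The block also called 1 chemokine up and 1 down, 1 glycolysis and hypoxia gene up and 1 CD8 T cell marker down. Mean, median and test differed in sign for the Th1, IL-2 and STAT5, cell cycle, CD4 marker and near-Ccr2 lists.

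**Figure D3:**
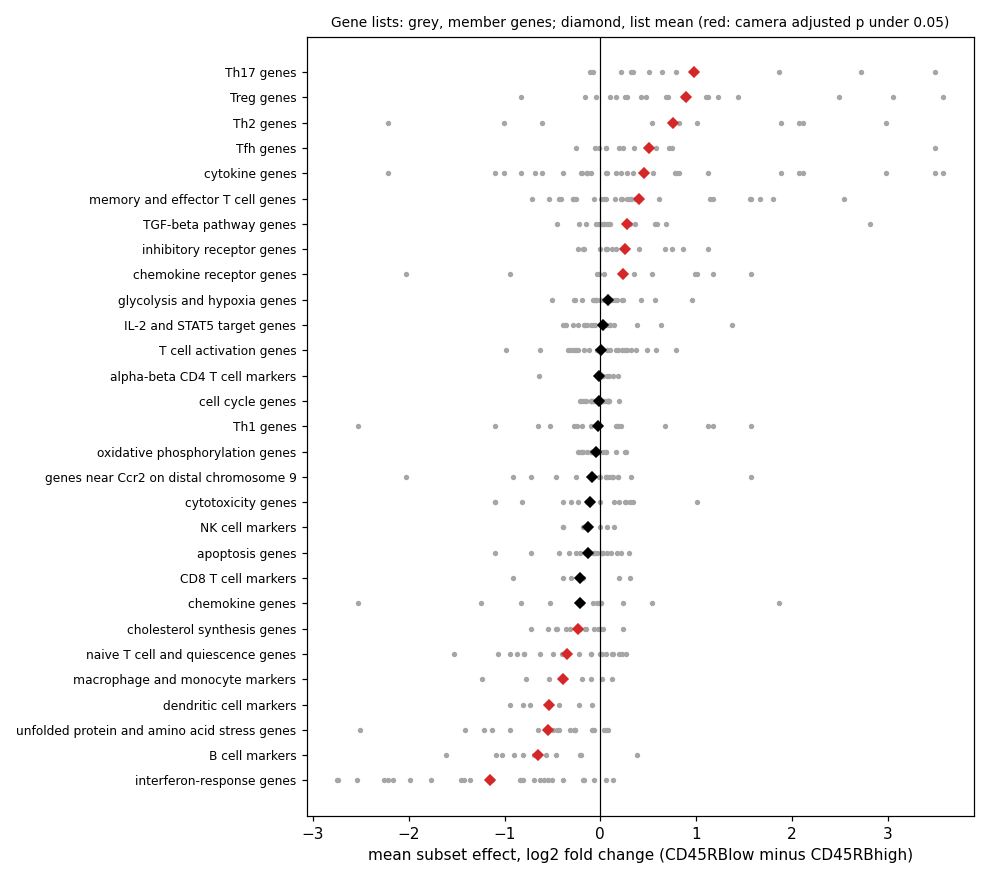
Log2 difference of CD45RBlow from CD45RBhigh cells, averaged over the genotypes (horizontal axis), for the 29 tested lists (vertical axis), with grey points for member genes and diamonds for list means, red where camera's adjusted p was under 0.05. List means ran from -1.15 for interferon-response genes to 0.97 for Th17 genes, and members of a list spread widely around its mean.

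At an unadjusted p under 0.05, 2446 genes differed between subsets, against 675.4 by chance. With the replicate number as a block 758 genes passed, 264 higher and 494 lower, and all 409 were among them. The count was 136 without wild-type CD45RBhigh replicate 1, 39 without wild-type CD45RBlow replicate 1, 69 without CCR2-/- CD45RBlow replicate 1, 122 without wild-type CD45RBhigh replicate 2, 112 without wild-type CD45RBlow replicate 2 and 239 without CCR2-/- CD45RBlow replicate 2. Camera called 16 of 29 lists, none of which held with an estimated correlation. In a fit with only a mean for each set of 4 arrays, the subset split called 14 lists and other splits into 4 and 4 up to 12.

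Within wild type, 12 genes passed between CD45RBlow and CD45RBhigh cells, 6 higher and 6 lower. Il1r2 (log2 2.85, adjusted p = 0.0298), Maf (2.60, adjusted p = 0.0207), Erg (2.02), Timp1, an inhibitor of metalloproteinases (1.99), Cd200r1 (1.62) and Spx (1.26) rose. Phf11b (-1.71), Oas1b, an interferon-induced gene (-1.46), H2-Q5 (-1.19) and Gramd3 (-1.11) fell. Foxp3 differed by 3.21 (adjusted p = 0.0610, and 0.0181 with the replicate block) and Il4 by 1.35 (adjusted p = 0.121, and 0.0171 with the block). Camera called 16 lists, led by interferon-response genes (mean -1.32, adjusted p = 5.44e-10; adjusted p = 0.358 with an estimated correlation), with 1 member lower adjusted over the list alone. Regulatory T cell genes (mean 0.997, adjusted p = 7.77e-10; adjusted p = 0.188 with an estimated correlation) had 8 members higher and 1 lower adjusted over the list alone, and 6 and 1 with the replicate block. Camera called apoptosis genes down here (mean -0.19, adjusted p = 0.0122; adjusted p = 0.188 with an estimated correlation), with 2 lower adjusted over the list alone and 1 with the block, a call lost without wild-type CD45RBhigh replicate 1 (adjusted p = 0.102) or wild-type CD45RBlow replicate 2 (adjusted p = 0.0719), while fry called the list in wild type (adjusted p = 0.0031) and in CCR2-/- cells (adjusted p = 0.0412). The block raised the count to 104, and 1245 genes had an unadjusted p under 0.05. Leaving out arrays gave 4 genes without wild-type CD45RBhigh replicate 1, 54 without CCR2-/- CD45RBhigh replicate 1, 57 without CCR2-/- CD45RBhigh replicate 2, 6 without either CCR2-/- CD45RBlow array, and 1 without any of the other 3, wild-type CD45RBlow replicates 1 and 2 and wild-type CD45RBhigh replicate 2.

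Within CCR2-/- cells, 45 genes passed, 19 higher and 26 lower in CD45RBlow cells. With array weights the order of the counts turned over, at 7 here and 116 in wild type. Akr1c18 (log2 3.94, adjusted p = 0.0229), Ahr (3.27), Gpm6b (3.02), Tnfrsf8, encoding CD30 (2.88), Itgb8 (2.84), Il1r2 (2.51), Maf (2.49), Il4 (2.42), Lrrk2 (2.31) and Erg (2.15) rose most. Ms4a4b (-3.55, adjusted p = 0.0352), Amigo2 (-2.45), Aldh1l2 (-2.38), Phf11b (-2.05), Ifi209 (-2.03), Atp8b4 (-1.96), Acsl6 (-1.67), Dapl1 (-1.60), Ctss (-1.42) and Niban1 (-1.40) fell most. Foxp3 differed by 2.90 (adjusted p = 0.0537, and 0.0173 with the replicate block) and Gata3 by 1.05 (adjusted p = 0.0596, and 0.0177 with the block). Il4 and Ccr4 (1.12) rose among 11 Th2 genes, 4 rose with the block, 8 were higher adjusted over the list alone, and the list was called up (mean 0.90, adjusted p = 1.16e-05; adjusted p = 0.352 with an estimated correlation). Its mean was 0.42 without CCR2-/- CD45RBhigh replicate 1 and 1.37 without CCR2-/- CD45RBhigh replicate 2. It was 1 of 16 lists called, among them CD8 T cell markers (mean -0.34, adjusted p = 0.0345; adjusted p = 0.352 with an estimated correlation), with 1 lower adjusted over the list alone. Camera also called B cell (mean -0.78, adjusted p = 0.0020), dendritic cell (-0.61, 7.58e-04) and macrophage and monocyte markers (-0.47, 0.0281) down. With an estimated correlation their adjusted p was 0.511, 0.352 and 0.352. Without CCR2-/- CD45RBhigh replicate 1 the B cell call (mean -0.30) and the macrophage and monocyte call (mean -0.34) were both lost. The macrophage and monocyte call was also lost without CCR2-/- CD45RBlow replicate 1 (mean -0.45). Without CCR2-/- CD45RBhigh replicate 2 the B cell mean was -1.28. The CD8 call was lost without CCR2-/- CD45RBhigh replicate 1 (mean -0.15, adjusted p = 0.604; the array with the highest CD8, B cell and macrophage marker means), CCR2-/- CD45RBlow replicate 1 (adjusted p = 0.0612) or replicate 2 (adjusted p = 0.172), or wild-type CD45RBhigh replicate 2 (adjusted p = 0.171). The block raised the count to 196, and 1665 genes had an unadjusted p under 0.05. The count was 12 without either wild-type CD45RBlow array, 1 without CCR2-/- CD45RBlow replicate 1, 98 without CCR2-/- CD45RBhigh replicate 2 and 5 without CCR2-/- CD45RBlow replicate 2.

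The log2 subset effects of the genotypes share no array, but both tests took each gene's variance from the same fit over all arrays. Of the genes called in each, 5 were higher in both and 5 were lower in both. Independent lists would share 0.0084 and 0.0115. These values are no baseline here, because a gene with a small spread in that fit is favoured in both lists. Across genes, which are not independent replicates, the effects correlated at r = 0.779.

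Between genotypes in CD45RBhigh cells, Casp1, the protease that processes interleukin 1 beta, had the smallest p. Its log2 level was 7.83 ± 0.04 in wild type and 6.42 ± 0.19 in CCR2-/- cells (mean ± SD, n = 2 each), a difference of -1.42 (95% confidence interval -1.71 to -1.12) that missed the threshold (adjusted p = 0.0934). Tmem181c-ps (1.53), Mctp1 (0.97), Blvrb (0.71), Rex2 (0.59), Acss2 (0.57) and Mvb12b (0.51) were higher in CCR2-/- cells, and Tnfrsf8 (-1.43), Mtmr7 (-0.69) and Ssxb8 (-0.58) lower, and none passed. Th2 genes were called down as a list (mean -0.50, adjusted p = 3.85e-05; adjusted p = 0.774 with an estimated correlation), with Il24 at -1.24 and Gata3 at -0.43, while none passed adjusted over the list alone. The Th2 mean rested on CCR2-/- CD45RBhigh replicate 1, without which it was -0.02 (adjusted p = 0.694). That array had the highest means of the 8 for B cell (6.90), CD8 T cell (5.81) and macrophage and monocyte markers (6.07). The Th2 mean was -0.25 without wild-type CD45RBhigh replicate 2 and -0.97 without CCR2-/- CD45RBhigh replicate 2. Limma called 0 genes, with 354 at an unadjusted p under 0.05 (573 with the replicate block) against 675.4 by chance, and 62 at that p with at least a 1.5-fold change. In simulated data of this comparison, 65 of 100 genes changed by 1 log2 unit were recovered. The simulated arrays lacked the differences between replicate numbers and had the same spread in all groups. This share is therefore not the share that the real arrays would recover.

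In CD45RBlow cells, Timp1 was at 6.74 ± 0.36 in wild type and at 5.38 ± 0.20 in CCR2-/- cells (mean log2 level ± SD, n = 2 each), a difference of -1.37 (95% confidence interval -1.80 to -0.93, adjusted p = 0.9998). Fyco1, a neighbour of Ccr2 that takes part in the transport of autophagosomes (1.09), Tmem181c-ps (1.12), Cd24a (0.77), Bex1 (0.61), Rab6b (0.55), Mlh3 (0.52) and Smarca5-ps (0.48) were higher in CCR2-/- cells, and Sostdc1 (-0.62) and Zbed5 (-0.45) lower, and none passed. Ifng differed by -1.40 (interval -2.56 to -0.24) and Il4 by 0.85 (interval 0.29 to 1.40). Camera called Th17 genes down (mean -0.40, adjusted p = 3.46e-04), with Ccr6 at -0.91, and follicular helper genes (mean -0.21) and cytokine genes (mean -0.26) down (adjusted p = 8.75e-04 each). Regulatory T cell genes (mean -0.17) and memory and effector genes (mean -0.07) were called down and cholesterol synthesis genes up (mean 0.14), at adjusted p = 0.0443 each; all 6 calls had adjusted p = 0.660 with an estimated correlation. Adjusted over the list alone, 1 follicular helper gene was lower and no member of the other 5 lists passed. With the replicate block the cholesterol call was lost (adjusted p = 0.0774), and Th1 (mean -0.14) and chemokine receptor genes (mean -0.14) were called down (adjusted p = 0.0444 each). Limma called 0 genes, with 298 at an unadjusted p under 0.05 (587 with the block) against 675.4 by chance, and 43 of at least 1.5-fold. All 6 list calls were lost without wild-type CD45RBlow replicate 1, where the means were -0.12 for Th17, -0.16 for follicular helper, -0.14 for cytokine, 0.02 for regulatory T cell, 0.04 for memory and -0.0014 for cholesterol synthesis genes. Without CCR2-/- CD45RBlow replicate 2 only the Th17 call held, and the means of the other 5, in that order, were -0.12, -0.15, 0.08, -0.0076 and 0.06. Without CCR2-/- CD45RBlow replicate 1 the memory call was lost (mean -0.14, adjusted p = 0.0611), and the regulatory T cell and cholesterol means were -0.45 and 0.23. Without wild-type CD45RBlow replicate 2 the means, all called, were -0.70 for Th17, -0.40 for cytokine, -0.39 for regulatory T cell, -0.19 for memory and 0.29 for cholesterol synthesis genes. Regulatory T cell, memory and cholesterol calls were also lost without CCR2-/- CD45RBhigh replicate 1 (adjusted p = 0.0555, 0.0555 and 0.0571) or replicate 2 (adjusted p = 0.0544 each).

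Averaged over the subsets, Casp1 differed between genotypes by -0.97 (95% confidence interval -1.18 to -0.76, adjusted p = 0.119), Tmem181c-ps by 1.33 (adjusted p = 0.746) and Fyco1 by 0.93 (interval 0.59 to 1.27, adjusted p = 0.940), the 1 gene of 19 near Ccr2 that was higher adjusted over the list alone. Erdr1 (1.30), Mctp1 (0.74), Bex1 (0.55), Rab6b (0.54) and Acss2 (0.49) were higher and Timp1 (-0.72) and Ssxb8 (-0.48) lower in CCR2-/- cells, and none passed. Foxp3 differed by -0.14 (interval -0.85 to 0.57), Il10 by -0.45 (interval -1.31 to 0.40) and Ifng by -0.999 (interval -1.82 to -0.18). Th2 (mean -0.36), Th17 (mean -0.31) and cytokine genes (mean -0.25) were called down at adjusted p = 7.83e-04 each, and follicular helper genes at adjusted p = 8.20e-04 (mean -0.21). With an estimated correlation these had adjusted p = 0.647 for Th2 genes and adjusted p = 0.630 for the other 3, and none of their members passed adjusted over the list alone. Cholesterol synthesis genes (mean 0.12, adjusted p = 0.0357, and 0.0566 with the replicate block) and NK cell markers (mean 0.16, adjusted p = 0.0478, and 0.0598 with the block) were called up. With an estimated correlation their adjusted p was 0.804 and 0.630. Of the NK cell markers, 1 was higher adjusted over the list alone, Klrc1 (0.33). These markers were dim, with list means of 4.53 to 4.93 on the arrays, near the 40th percentiles of 4.53 to 4.63. Klrc1 lay between 4.32 and 4.87. Without CCR2-/- CD45RBhigh replicate 1, the array with the highest B cell, CD8 and macrophage marker means, the Th2 (mean -0.12), cytokine (mean -0.13) and cholesterol (mean 0.08) calls were lost. The Th2 mean was -0.24 without wild-type CD45RBhigh replicate 2 and -0.60 without CCR2-/- CD45RBhigh replicate 2, and the Th17 mean was -0.20 without wild-type CD45RBhigh replicate 1 and -0.19 without wild-type CD45RBlow replicate 1. The cholesterol call was also lost without wild-type CD45RBlow replicate 1 (mean 0.05), CCR2-/- CD45RBlow replicate 2 (mean 0.08) or wild-type CD45RBhigh replicate 2 (mean 0.10), and its mean was 0.19 without wild-type CD45RBlow replicate 2. The NK cell marker call held only without wild-type CD45RBhigh replicate 2 or wild-type CD45RBlow replicate 2, and its adjusted p was 0.0621 to 0.204 without any other array. Chemokine receptor genes were called down only with the block (mean -0.11, adjusted p = 0.0342). Limma called 0 genes, with 521 at an unadjusted p under 0.05 (967 with the block) against 675.4 by chance, and 18 of at least 1.5-fold. The fit without the block counts the shared replicate difference as spread. Its count under 675.4 therefore does not show that the genotypes are alike. The genotype effects of the subsets correlated across genes at r = 0.294.

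**Figure D4:**
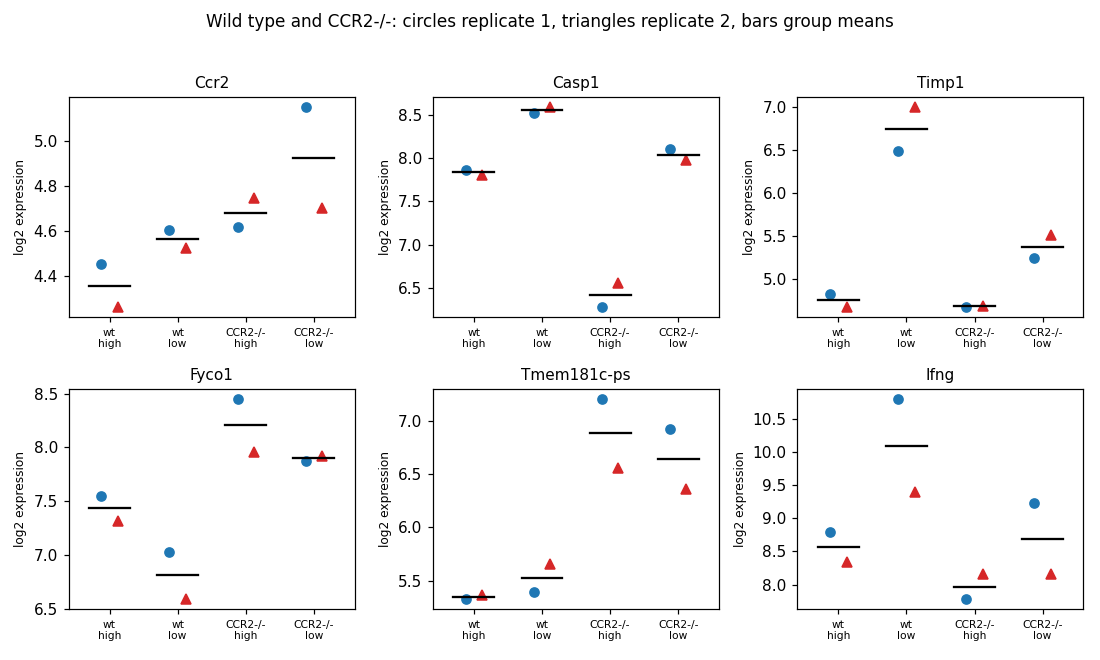
Log2 expression (vertical axis) of 6 genes in the 4 groups (horizontal axis), where each point is an array, circles are replicate 1, triangles are replicate 2 and bars are group means of 2 arrays. Ccr2 stayed between 4.26 and 5.15 on all arrays, and Casp1 was lowest in CCR2-/- CD45RBhigh cells (6.42), although no gene passed between genotypes.

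The interaction asked whether the genotype difference depended on the subset. Casp1 had an interaction of 0.90 (interval 0.48 to 1.32), the genotype difference in CD45RBlow minus that in CD45RBhigh cells, and Timp1 of -1.29 (interval -1.90 to -0.68). Tmem35a (0.92), Zfp382 (0.80), Pcnx4 (0.56) and Abcb10 (0.46) were positive, and Speer4a (-0.69), Rex2 (-0.57), Tacc1 (-0.56) and Gpr34 (-0.56) negative. Il4 had an interaction of 1.06 (interval 0.28 to 1.85) and Foxp3 of -0.31 (interval -1.72 to 1.10). None of these passed (adjusted p = 0.9998 each), and limma called 0 genes, with 160 at an unadjusted p under 0.05 (288 with the replicate block) against 675.4 by chance, and 58 of at least 1.5-fold. CD8 T cell markers were called as a list (mean -0.25, adjusted p = 0.0427; adjusted p = 0.896 with an estimated correlation), with none of 6 members passing adjusted over the list alone. The call was lost without CCR2-/- CD45RBhigh replicate 1 (mean -0.08), wild-type CD45RBhigh replicate 2 (mean -0.13), CCR2-/- CD45RBlow replicate 1 (mean -0.27) or CCR2-/- CD45RBlow replicate 2 (mean -0.23), and the mean was -0.39 without CCR2-/- CD45RBhigh replicate 2. Th2 genes were called only with the replicate block (mean 0.28, adjusted p = 0.0819, and 0.0344 with the block).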

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

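All tests in this part were fixed before the data were examined. The test of the difference between subsets picked out CD8 T cell markers, whose genotype effect was lower in CD45RBlow than in CD45RBhigh cells by -0.25 on average over 6 genes (camera adjusted p = 0.0427, adjusted p = 0.896 with an estimated correlation). All 6 members had a negative interaction. It was 1 of 29 lists tested, and no gene of the list passed. The call was lost without CCR2-/- CD45RBhigh replicate 1 (-0.08, adjusted p = 0.789), wild-type CD45RBhigh replicate 2 (-0.13, adjusted p = 0.595), CCR2-/- CD45RBlow replicate 1 (-0.27, adjusted p = 0.121) or CCR2-/- CD45RBlow replicate 2 (-0.23, adjusted p = 0.160), and the mean was -0.39 without CCR2-/- CD45RBhigh replicate 2. CCR2-/- CD45RBhigh replicate 1 had the highest mean of the 8 arrays not only for CD8 T cell markers (5.81) but also for B cell markers (6.90) and macrophage and monocyte markers (6.07).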

How the results depend on the processing

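Leaving out both CCR2-/- replicate 2 arrays, and leaving out X and Y chromosome genes, were alternatives chosen after the data were seen. For each genotype effect and the interaction, limma called 0 genes under every alternative run (the fit on only the compared groups was run for the 4 effects between 2 groups) except unadjusted p under 0.05 with a 1.5-fold change, which gave 62 genes in CD45RBhigh, 43 in CD45RBlow, 58 for the interaction and 18 for the averaged genotype effect; leaving out arrays gave 0 to 0 in each. For the subset effect in wild type (12 genes), counts were 24 with median centring, 31 with a variance trend, 116 with array weights, 104 with the replicate block, 36 with only the compared groups, 1 with every transcript cluster, 36 without both CCR2-/- replicate 2 arrays, 455 with unadjusted p and fold, and 1 to 57 leaving out arrays. For the subset effect in CCR2-/- cells (45 genes), the same settings gave 83, 69, 7, 196, 9, 2, 19, 566 and 1 to 98. The averaged subset effect (409 genes) gave 758 with the replicate block, 77 with every transcript cluster and 39 to 547 leaving out arrays, and stayed within 1.5 times under the others run. Every transcript cluster means more tests, and left-out arrays mean fewer samples; a group left with 1 array is assumed to vary like the others. For the remaining settings the cause was not tested. The larger count in CCR2-/- than in wild-type cells turned over with array weights (7 against 116) and with only the compared groups (9 against 36). The array weights were 0.58 and 0.81 in the CCR2-/- groups and 1.20 and 1.76 in the wild-type groups. The 45 and 12 genes therefore do not show that more genes differ in CCR2-/- cells.

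Of 62 list calls, 0 held with camera's estimated correlation, fry called 16, of which 14 are shared, and leaving out arrays gave 45 to 80, keeping between 41 (without CCR2-/- CD45RBhigh replicate 1) and 60 (without wild-type CD45RBlow replicate 2). The replicate block kept 58; the 4 lost and the lists it added are given with their comparisons. The lists whose means turned over are all genotype effects in CD45RBlow: regulatory T cell genes at 0.0845 without CCR2-/- CD45RBlow replicate 2 and also without both CCR2-/- replicate 2 arrays (-0.4508 to 0.0845 leaving out arrays), and, without wild-type CD45RBlow replicate 1, memory and effector genes at 0.0411 (-0.1907 to 0.0411) and cholesterol synthesis genes at -0.0014 (-0.0014 to 0.2887). Without that array the regulatory T cell mean was 0.0228 while camera, which gives a list its direction here, still ranked it down; the cause was not tested beyond the fewer samples. Of the 93 calls of named genes, the replicate block kept 93 and quantile normalization 93. Leaving out wild-type CD45RBhigh replicates 1 and 2 kept 47 and 45, wild-type CD45RBlow 26 and 36, CCR2-/- CD45RBhigh 67 and 76, and CCR2-/- CD45RBlow 25 and 44. Of 473 pairs of a gene and a comparison that the naming rule examined and that were not called, the block called 36, all subset effects. A gene can count in several comparisons. The block changed no other call beyond those given. Median centring and quantile normalization moved the median gene effect by at most 0.054. Dim genes, such as Ccr2 on most arrays, limit what the arrays can show.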

Other observations

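The tests of the sex-linked genes, of B cell RNA and replicate number for the interferon-response genes, of donor DNA around Ccr2, and of splits for the genotype gene count were chosen after the result was seen. Besides the sex-linked genes, the replicate number was tested over all genes. With the number as a term, limma called 9 genes, 5 higher and 4 lower on the replicate 2 arrays, and 5 of the 9 lie on a sex chromosome. Xist was higher by 7.23 on the log2 scale, Mid1 by 2.25, Stra6 by 1.55, Pparg, a nuclear receptor, by 0.99, and Itga4, the integrin alpha 4 subunit, by 0.83. Kdm5d differed by -1.28, Eif2s3y by -1.21, Uty by -1.04 and Srgap3 by -1.30. These genes are named because the count is small, and were chosen after their values were seen. At an unadjusted p under 0.05, 2194 genes differed by number, against 675.4 by chance. The difference between numbers was therefore not confined to the 9 called genes.

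The subset difference was set against other splits of the 8 arrays into 4 and 4, in a fit with a mean for each set of 4. For genes, 1 of 35 splits called as many as the 699 of the real subset split, namely that split itself. The highest other was 7, for the split by replicate number. This is a share under 0.05, the bound set beforehand against chance. Among the 18 splits that part the numbers evenly the highest other was 0. With the numbers taken to pair the samples, only these 18 count, and they are too few for a share under 0.05. For gene lists, the real split called 14 and the highest other 12, again with 1 of 35 as large, but 31 of the 34 other splits called at least 1 list, with a median of 5. Splits that part the subsets or the numbers unevenly carry some of those differences, so these counts give no rate of chance calls for the 4-group fit. Of the 62 list calls of that fit, 0 held with an estimated correlation, so a called list carries little weight by itself. For the genotype, the real split called 0 genes, a count that all 35 splits reach whatever the data, so it tests nothing. The real genotype split called 3 lists in this fit, against 6 in the fit with 4 groups. Of the 35 splits 24 matched it, and the highest other was the subset split with 14. Because these splits ignore the subset and some carry its difference, they are no baseline of chance. They neither exclude chance for the genotype's lists nor show it.

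The first pattern is the difference between replicate numbers that the 4 groups share. Xist was higher on the replicate 2 array in each group, by at least 6.87, while Kdm5d, Uty and Eif2s3y were lower in each, which is consistent with a different sex makeup of the mice behind each number. Y-linked transcripts stayed high on the replicate 2 arrays, so a candidate explanation is RNA from mice of both sexes there. Sex-linked genes are not the whole cause, since without X and Y chromosome genes the median of the 6 correlations was still 0.240, although the lowest was 0.055. What else the number marks stays open, and no biological explanation beyond sex was tested.

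The second pattern is the lower mean of interferon-response genes in CD45RBlow cells. RNA of B cells could raise such genes in CD45RBhigh samples. The mean B cell marker gap was smaller among replicate 2 arrays, by 0.97 on average over both genotypes, where the interferon gap was larger. The list mean thus runs against B cell RNA for those arrays. The gap of Ighm went the other way, but in CCR2-/- cells only slightly (10.86 to 9.77 in replicate 1, 10.82 to 9.64 in replicate 2). The gaps of Fcer2a, H2-Aa and H2-Eb1 went with the list mean in both genotypes. The markers therefore do not decide the question for those arrays. Among replicate 1 arrays the mean B cell gap was -1.14 on average. It was larger in CCR2-/- cells (-1.32, interferon gap -0.16) and smaller in wild type (-0.95, interferon gap -1.03). This order runs against B cell RNA but rests on 1 pair of arrays each. For either replicate number, B cell RNA cannot be told apart from a lower interferon response of CD45RBlow T cells, which remains a hypothesis. The sort for CD4+ cells should remove B cells, Ighm alone passed among the B cell markers (10.7 in wild-type CD45RBhigh cells), and 3 of the 11 tested are MHC class II genes that other antigen-presenting cells share. Each group holds an array of each number, so a difference between numbers that the groups share cancels from the gap by design and was not tested by the gaps within each number and genotype, the smallest -0.16, with a mean of -1.15 and an SD of 0.74.

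The third pattern is the genotype effect near the targeted locus, where DNA from the donor strain of a knockout might remain. Fyco1 was the only one of 19 tested neighbours of Ccr2 with an unadjusted p under 0.05 in the averaged genotype effect (it also passed adjusted over the list alone, there and in CD45RBlow cells), against a mean of 0.836 in 10000 random lists matched on expression, at percentile 60.9. Between Casp1 and Ccr2, which lie on the same chromosome in GRCm38.p6, 25 of 752 genes had such a p, against a mean of 28.2, at percentile 27.0. Counting ties at mid-rank and asking for a value beyond the random spread were settled after the values were seen; a count under the 50th percentile had been set as the bound against a donor segment, but one this close to the random mean excludes nothing, since a segment need not change many genes. Casp1 is no close neighbour of Ccr2, since these 752 tested genes lie between them. Neither Casp1 (adjusted p = 0.119) nor Fyco1 (adjusted p = 0.940) passed limma's test over all genes in the averaged genotype effect. Donor DNA, an effect of CCR2 loss and chance therefore cannot be told apart for Fyco1 and Casp1.

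A hypothesis that CCR2 loss shifts cells away from the CD45RBlow profile was tested across genes. The averaged genotype and subset effects correlated at r = -0.35, but 2 of 18 relabellings of the genotypes within each subset gave a correlation of that size or more, the real labels included, and the highest other was 0.44. The relabellings ignore the replicate number, so some follow its difference, and they are too few for a share under 0.05. They do not decide the question.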
